A study of Mus musculus with 39 samples.

How the data were processed

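The samples were 20 libraries of CD8+ T cells sorted from MCA-205 tumours and 19 libraries labelled bulk tumour, from mice given FMT in a CZA or a CZA+DAV132 arm and treated with anti-PD-1 or an isotype antibody. Per the labels' protocols, total RNA was taken with a Monarch kit, 300 ng were depleted of ribosomal RNA with RiboCop, and strand-specific libraries were made with the NEBNext Ultra II Directional kit. Groups and replicate names were taken from the sample titles and treatment labels.

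Expression was deposited as TPM, with a table for each set. Per the submitters' processing notes, kallisto 0.45 and the mouse build GRCm38 were used. The annotation and the way transcripts were summed to genes are not given in the sources used here. Each table held 28023 gene symbols without identifiers, of which 27787 were matched by symbol to GENCODE M21, an annotation of GRCm38, and 21036 of those were protein coding. Gene identifiers and coordinates come from that match. The tables were analysed separately, since they may have been normalised separately, and levels set side by side across them carry that limit. All value columns were used, and no columns were identical within a set. TPM holds no read counts, so neither depth nor counting error could be given, and a gene listed at 0 is given as listed at 0. Kallisto shares reads among transcripts that match alike, so genes with near-identical copies or with repeats in their transcripts are uncertain.

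TPM values were put on the log2(TPM + 1) scale, and fold changes are on that scale, which understates the change of low genes. Genes with at least 1 TPM in at least 4 libraries of a set were tested, 12942 in the CD8 set and 13326 in the other. A linear model with a mean for each of the 4 groups was fitted in each set with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, so that all groups share an estimate of the spread. There were 7 contrasts per set: DAV132 against no DAV132 under each antibody, anti-PD-1 against isotype in each arm, their interaction, and both effects averaged. P-values were two-sided, were adjusted over genes with the Benjamini-Hochberg method, and were called under 0.05. Lists of genes, 18 of function and 14 of cell type markers, with 677 symbols, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and by exact permutation of the list mean in pairwise contrasts, where 5 against 5 and 4 against 5 libraries allow no p below 0.00794. No list passed after adjustment in the exact tests. These tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

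Genes are named by a rule. In each contrast it took the 10 largest rises and the 10 largest falls among the genes called with a mean of at least 5 TPM, or all if fewer. Where fewer than 3 passed in a direction, it took the 3 of smallest p with a mean of at least 5 TPM, given as not passing. It also took the 3 members of smallest p in each list called by camera, and 18 genes in every contrast: Cd8a, Cd3e, Cd4, Foxp3, Pdcd1, Havcr2, Lag3, Tox, Tcf7, Slamf6, Ifng, Gzmb, Prf1, Mki67, Cxcl9, Cxcl10, Cd274 and Madcam1. Predicted genes, pseudogenes, histone genes, antigen receptor segments, mitochondrial genes and small non-coding RNAs were left out of the first parts of the rule. The text describes part of the genes so taken.

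The method was tested on simulated values for the tested genes of each contrast, with 200 genes changed in each of 5 runs. The changed genes were drawn from those with a mean log2 level above that of 5 TPM. Values varied independently between genes, with the same spread in all groups. In the CD8 set, among 12942 genes, the share of genes recovered at a log2 fold of 1 and of 2 was 31.4% and 93% for DAV132 under anti-PD-1, 32.2% and 91.6% for DAV132 under isotype, 33.6% and 93.4% for anti-PD-1 in CZA, and 34.6% and 94% for anti-PD-1 in CZA+DAV132. It was 8.2% and 60.8% for the interaction, 76% and 98.2% for averaged DAV132, and 76.8% and 97.6% for averaged anti-PD-1. In the libraries labelled bulk tumour, among 13326 genes, it was in the same order 5.4% and 42.4%, 4.2% and 33.2%, 6.2% and 41.4%, 4.4% and 38%, 0.2% and 8%, 23.6% and 73%, and 21.8% and 70.6%. Unchanged genes made up 3.24% to 6.5% of the simulated calls, and 10.9% for the interaction in the libraries labelled bulk tumour. A list shifted by 0.5 was called in each of the 14 contrasts, and 2 of 434 other lists were. In the data, genes vary together and libraries differ in spread, so the shares of false calls and of other lists called need not hold there. The shares recovered apply to genes above that level only.

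The alternatives were a fit of only the groups compared, a pseudocount of 0.1, no filter, a stricter filter of a mean of 5 TPM, median-ratio scaling over genes above 0 in every library, TPM rescaled without mitochondrial genes and small non-coding RNAs, limma's array weights, and each library left out in turn. After the data were seen, fits were added without CD8 libraries 16 and 19, with and without median-ratio scaling, without T985 and T026 of the libraries labelled bulk tumour, and with TPM rescaled without 15 repeat entries. Of those entries, 12 share at least 5% of their words of 31 bases with the satellite transcript of Gm10800, and 3 are short transcripts in which at most 70% of such words are distinct. Each contrast was also fitted for 100 splits of its libraries, the real split included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Fragment length, read strand and mapping rates were not used here.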

Results

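C57BL/6 mice, a common inbred laboratory strain, received faecal microbiota transplants (FMT) of stool from human volunteers exposed for 6 days to CZA alone or to CZA with DAV132. The labels name CZA only by this abbreviation, and DAV132 is an adsorbent that acts in the colon. MCA-205 cells, a mouse fibrosarcoma line of the same strain, were injected under the skin 2 weeks later. Mice with tumours of 25 to 35 mm2 were given 4 injections, 3 days apart, of 250 µg of anti-PD-1, an antibody that blocks an inhibitory receptor of T cells, or of an isotype control. Tumours were collected 2 days after the final injection. The comparisons asked how the transcripts differed between the FMT arms under each antibody, and how anti-PD-1 differed from isotype within each arm, in a study of whether DAV132 lessens the resistance to anti-PD-1 that goes with antibiotics. A first experiment gave 19 libraries labelled bulk tumour, and a repeat with the same FMT material gave 20 libraries of CD8+ T cells sorted from tumours. Each group held 5 libraries, except the CZA+DAV132 isotype group of the bulk tumour set, which held 4. Values were deposited as TPM, transcript abundance scaled to a fixed total per library, which keep no record of sequencing depth, so the depth behind each value is unknown. The TPM of the listed genes summed to between 956720 and 989078 per library in the CD8 set and to between 970406 and 991092 in the bulk tumour set. The labels do not tie each library to its own mouse, so the p-values measure the spread between these libraries, part of which may be technical. The FMT arms differ in the stool given, which the libraries do not replicate. The DAV132 and interaction contrasts therefore cannot tell DAV132 from other differences between the stools. In the bulk tumour set the CZA libraries are named T982 to T991 and the CZA+DAV132 libraries T021 to T030, so anything that goes with these names also differs between the arms.

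T cell transcripts were abundant in the libraries labelled bulk tumour as in the sorted CD8 T cells, some of them at similar levels. Cd8a, which encodes a chain of the CD8 co-receptor, had a median of 352 TPM in the libraries labelled bulk tumour and 268 TPM in the CD8 set. Cd3e, a subunit of the T cell receptor complex, had medians of 419 and 750 TPM, and Pdcd1, which encodes PD-1, had medians of 129 and 111 TPM. Other genes that T cells express differed more. Trac had medians of 654 and 1534 TPM, Nkg7 of 1329 and 4946 TPM and Ptprc of 501 and 178 TPM, in the same order. Collagen Col1a1, an abundant product of fibrosarcoma cells, reached a median of only 13.0 TPM in the libraries labelled bulk tumour and 3.39 TPM in the CD8 set. The summed TPM of the T cell marker list was a median of 14.9 times that of the fibroblast and fibrosarcoma list in the libraries labelled bulk tumour, and exceeded it in each of the 19. The corresponding median ratio in the CD8 set was 34.8. The macrophage genes Lyz2 and C1qa had medians of 79.5 and 3.38 TPM in the libraries labelled bulk tumour against 136 and 22.8 TPM in the CD8 set. The keratin Krt14 had a median of 0 TPM in both sets. The sets were not alike in all genes, since Actb, which encodes a cytoskeletal actin, had medians of 107700 TPM in the libraries labelled bulk tumour and 4382 TPM in the CD8 set. Because these levels go against a whole-tumour label, the set is called the libraries labelled bulk tumour throughout. Madcam1, an adhesion molecule for gut-homing T cells, was listed at 0 in all 19 of them and had a median of 0 TPM in the CD8 set, where the highest library had 0.528 TPM.

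**Figure D1:**
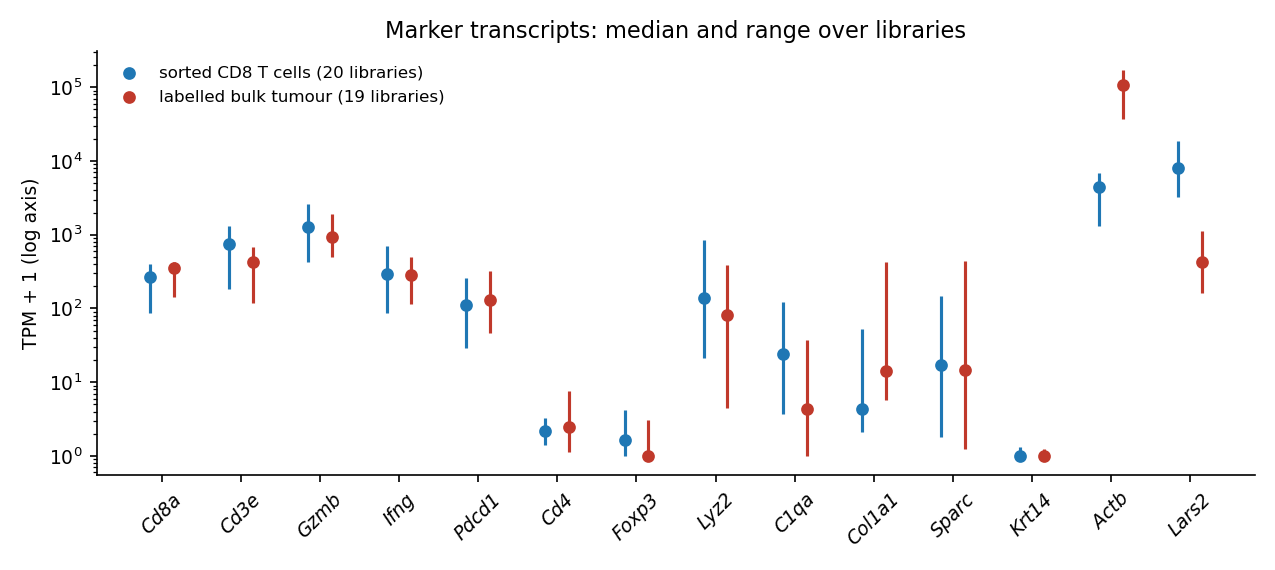
Levels of marker genes in the CD8 set (20 libraries) and in the libraries labelled bulk tumour (19 libraries), as TPM + 1 on a log axis, with dots for medians and lines for the range over libraries. Cd8a has medians of 268 and 352 TPM and Col1a1 of 3.39 and 13.0 TPM in the CD8 set and the libraries labelled bulk tumour, whereas Actb has 4382 and 107700 TPM.

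A share of the TPM fell on 15 gene entries made of repeats, 12 of satellite sequence and 3 of simple repeats, such as Gm10800 (GRCm38 chromosome 2, 98666547 to 98667301) and Gm17604 (chromosome X, 165003765 to 165004829). In the CD8 set these entries took 28.2% ± 23.8 (SD, n = 5) of the TPM in the CZA+DAV132 anti-PD-1 group and 4.15% ± 2.61 (n = 5) in the CZA+DAV132 isotype group, a difference with an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 libraries allow. They took 9.36% ± 10 (n = 5) in the CZA isotype group and 9.06% ± 4.67 (n = 5) in the CZA anti-PD-1 group. CD8 library 1 of the CZA isotype group had 25.2%. CD8 library 19 had 69.2% and library 16 had 28.3%, and both belong to the CZA+DAV132 anti-PD-1 group. Ribosomal protein transcripts made up 7.41% of the TPM in that group and 11.5% in the CZA+DAV132 isotype group (exact p = 0.00794). Among the libraries labelled bulk tumour, T026 of the CZA+DAV132 anti-PD-1 group had 50.9% and T985 of the CZA isotype group had 13.5%. Because TPM is a share, a library rich in repeats shows lower values for other genes, and each comparison is given with the median log2 change of all tested genes.

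**Figure D2:**
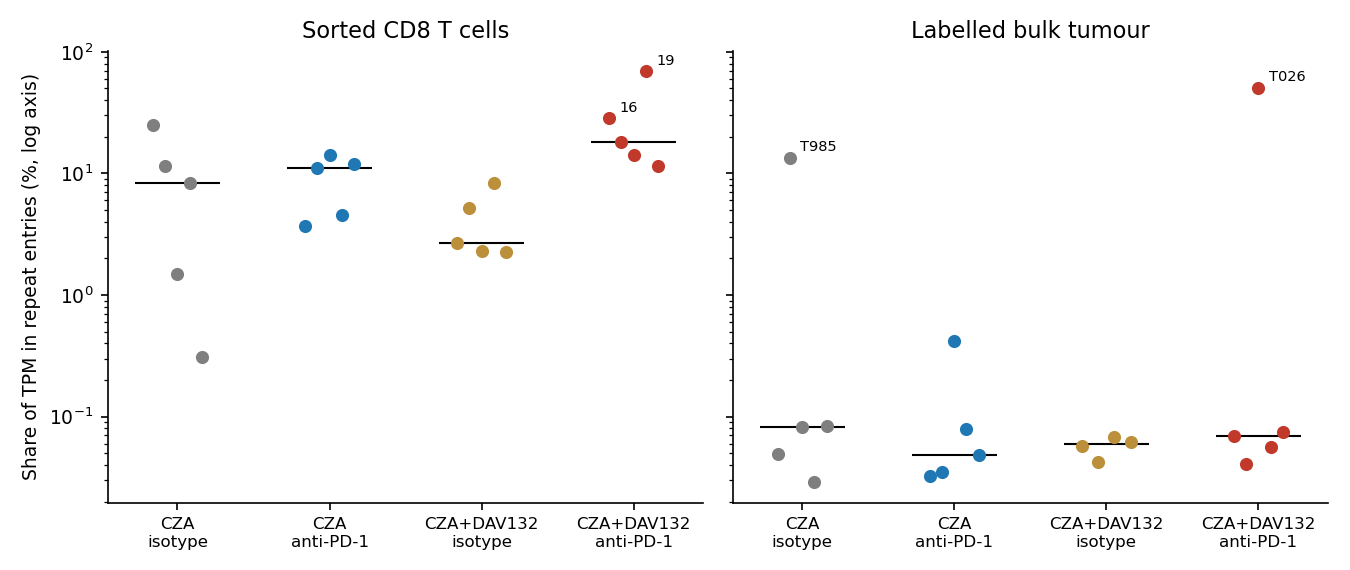
Share of TPM in the 15 repeat entries for each library, in percent on a log axis, by group, with a point for each library and a line at the group median. CD8 libraries 16 and 19 and libraries T985 and T026 of the set labelled bulk tumour are named, at 28.3%, 69.2%, 13.5% and 50.9%.

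Anti-PD-1 was compared with isotype in CD8 T cells of the CZA+DAV132 arm, and this contrast had the most calls of the 14. Ccl17, a chemokine of dendritic cells (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036), fell by 3.06 on the log2 scale (SE 0.61, limma adjusted p = 0.00653), from 11.6 to 0.218 TPM. Csf2, the cytokine GM-CSF (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667), fell from 102 ± 23.1 to 21.6 ± 26.1 TPM (SD, n = 5 and 5; log2 change −2.73, limma adjusted p = 0.00507). Ccr7, a homing receptor of naive and memory T cells and of mature dendritic cells (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), fell from 44.2 ± 17.9 to 9.02 ± 7.59 TPM (log2 change −2.39, adjusted p = 0.0052). Cd83, an activation marker of dendritic cells and lymphocytes (ENSMUSG00000015396, chromosome 13, 43784775 to 43803132), fell from 13.4 ± 4.74 to 2.10 ± 1.87 TPM (log2 change −2.40, adjusted p = 0.00395). In each of these genes all 5 anti-PD-1 libraries lay below the isotype mean. Dusp1, an immediate early phosphatase, Rgs2, Cd70, Tff1, Tcrg-C4 and the NK receptor gene Klra1 completed the 10 largest falls, with log2 changes from −2.88 to −2.40.

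Mitochondrial respiration genes were the most uniform group in this contrast. Of 44 measured members of the oxidative phosphorylation list, 38 fell and none rose, and 42 fell when adjusted over the list alone. Examples were Ndufa4 (1319 to 446 TPM, log2 change −1.69, adjusted p = 0.0068) and Cox7a2 (822 to 335 TPM, −1.43, adjusted p = 0.00653). Immediate early and heat shock genes followed, with 17 of 24 lower, 20 when adjusted over the list alone, among them Atf3 (−2.08) and the chaperone Dnaja1 (−1.42). The NK cell list had 9 of 14 members lower, 11 adjusted over the list alone, including the inhibitory receptors Klra3 (−1.95) and Klra9 (−2.02). The cell cycle list had 17 of 46 lower, 20 adjusted over the list alone, with the DNA synthesis genes Tyms (−1.69) and Gins2 (−1.55). Cholesterol synthesis had 9 of 22 lower, 10 adjusted over the list alone, with Fdps (−1.68), Stard4 (−1.20) and Pmvk (−1.20). MHC class II presentation had 6 of 12 lower, 7 adjusted over the list alone, with H2-Oa (−1.75) and H2-DMa (−1.59). Camera placed these 6 lists below the other genes (adjusted p between 1.43e-10 and 0.0416), and for each of them the adjusted p = 0.783 with an estimated correlation. The interferon gamma response list was placed above the other genes (adjusted p = 0.0333, and adjusted p = 0.783 with an estimated correlation), although its mean change was −0.02 and its median 0.04. Cxcl9, an interferon-induced chemokine that attracts T cells, rose from 3.16 to 8.91 TPM (log2 change 1.15, SE 0.37, adjusted p = 0.0308). 1 member of this list rose and 1 fell, against 0 and 1 when adjusted over the list alone.

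Several T cell identity and function genes did not pass in the same contrast. Cd8a had a log2 change of −0.58 (adjusted p = 0.183), Pdcd1 −0.59 (0.291), Ifng −0.52 (0.351), Gzmb −0.46 (0.368), Mki67 −0.23 (0.55) and Tcf7, a transcription factor of memory-like T cells, −1.01 (0.0774). The exhaustion genes Tox and Havcr2 had log2 changes of 0.48 (adjusted p = 0.149) and 0.66 (0.233). With median-ratio scaling, which removes the drop in the median gene, they had 0.95 (adjusted p = 0.0036) and 1.14 (0.0357), and Cd274, the PD-1 ligand, had 1.14 (0.0197). All of these 3 genes hold a dinucleotide repeat stretch in a transcript, in the group with the highest repeat share. The largest rises were in C1qtnf1 (ENSMUSG00000017446, chromosome 11, 118428203 to 118449963; 5.28 to 60.4 TPM, log2 change 3.60, adjusted p = 0.00886), Myo7a (156 to 1144 TPM, 3.13, adjusted p = 0.0372), Mid2, Sh3bgr and Nol3. A transcript with a stretch of at least 31 bases of dinucleotide repeat was annotated for 8 of the 10 largest rises. Without libraries 16 and 19, C1qtnf1 had an adjusted p of 0.0557, Myo7a of 0.168 and Cxcl9 of 0.139, while each of the 10 largest falls passed.

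Limma called 533 genes higher and 2509 lower in this contrast of 12942 tested, with a median change of all genes of −0.34. Median-ratio scaling gave 1548 higher and 1743 lower, TPM rescaled without repeat entries 1349 and 1265, and leaving out libraries 16 and 19 gave 542 higher and 665 lower. A fit of only the groups compared gave 427 higher and 854 lower. The relative change, after subtracting the median of all genes, had a mean of −0.75 for oxidative phosphorylation and −0.91 for immediate early and heat shock. It was −0.98 for the NK cell list and −0.35 for the T cell list, so none of these directions turned. Genes of higher level fell more, with a median of −0.535 under the stricter filter. Subtracting that median would leave less of each change, and least for the T cell list. The count was 1798 without library 15 and 1795 without library 16.

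**Figure D3:**
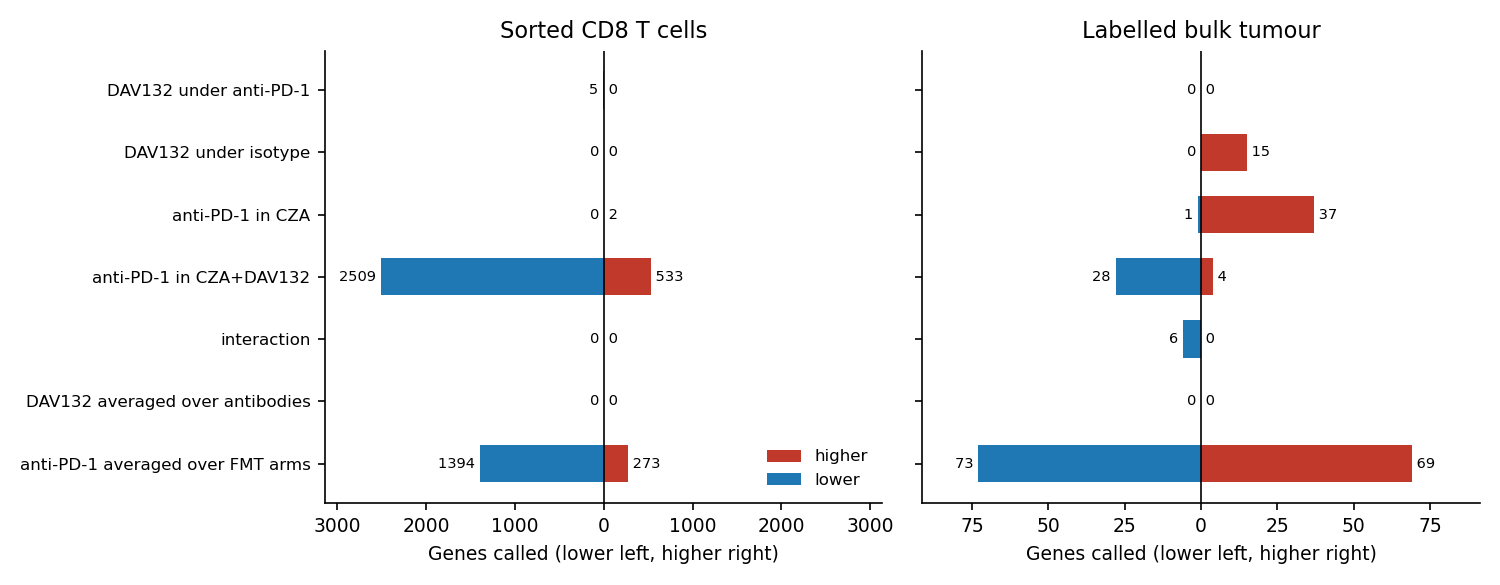
Genes called higher and lower by limma (adjusted p under 0.05) in each comparison, as bars starting at 0, for the CD8 set and the libraries labelled bulk tumour, with a different horizontal scale for each set. Anti-PD-1 in the CZA+DAV132 arm has 533 higher and 2509 lower in the CD8 set, and 4 higher and 28 lower in the libraries labelled bulk tumour, balances that turn to 1349 and 1265 and to 65 and 39 with TPM rescaled without repeat entries.

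In the CZA arm, anti-PD-1 against isotype in CD8 T cells gave no named gene past the threshold. By mean change, the macrophage and monocyte list and the MHC class II list stood lowest among the lists. Cd74, the invariant chain of MHC class II, had 407 TPM with isotype and 139 TPM with anti-PD-1 (log2 change −1.49, limma adjusted p = 0.637). Tyrobp, a signalling adaptor of myeloid and NK cells, had 250 and 90.4 TPM (−1.35), and Cd83 had 11.6 and 3.52 TPM (−1.54, adjusted p = 0.401). The macrophage and monocyte list of 22 members had a mean change of −1.11, with 0 members lower over all genes and 15 when adjusted over the list alone. The MHC class II list of 12 had a mean of −1.05, with 0 and 12. For both lists the camera result (adjusted p = 2.56e-16 and 7.6e-14) had an adjusted p = 0.203 with an estimated correlation. The NK cell list (mean −0.61, 0 of 14, 5 adjusted over the list alone) included Klrb1c at −1.25, with camera adjusted p = 2.06e-05 and adjusted p = 0.629 with an estimated correlation. The dendritic cell list of 15 had a mean of −0.55 with 0 members lower either over all genes or adjusted over the list alone (camera adjusted p = 1.54e-05, and adjusted p = 0.203 with an estimated correlation). Inhibitory receptor and exhaustion genes were placed above other genes (mean 0.29, 0 of 21 members passing, camera adjusted p = 0.000446, and adjusted p = 0.97 with an estimated correlation), with Havcr2 at 0.76, Prdm1 at 0.70 and Tox2 at 0.60. The type I interferon response list had a mean of −0.35 with Oasl1 at −1.28 (camera adjusted p = 1.54e-05, and adjusted p = 0.97 with an estimated correlation), and 0 of its 37 members passed either way. Limma called 2 genes higher and 0 lower, both predicted genes outside the rule for names, with 661 genes at an unadjusted p under 0.05, and with no filter it called 0, with 957 at an unadjusted p under 0.05. The median change of all genes was −0.02, and the count was 1 without library 1, 3 or 6 and 0 without each of the other libraries in the contrast.

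The comparison closest to the question of the study set CZA+DAV132 against CZA in CD8 T cells under anti-PD-1. Hilpda, a lipid droplet protein induced by hypoxia (ENSMUSG00000043421, chromosome 6, 29272488 to 29275446), fell from 167 ± 87.4 TPM in the CZA arm to 38.1 ± 15.3 TPM with DAV132 (SD, n = 5 and 5; log2 change −2.08, SE 0.37, limma adjusted p = 0.0329). Coa7, a factor for assembly of cytochrome c oxidase (ENSMUSG00000048351, chromosome 4, 108328140 to 108341544), fell from 19.8 ± 3.68 to 5.80 ± 3.08 TPM (−1.76, SE 0.30, adjusted p = 0.0306). Fosl2, a subunit of the AP-1 transcription factor (ENSMUSG00000029135, chromosome 5, 32135801 to 32157842), fell from 20.2 ± 5.52 to 6.45 ± 2.42 TPM (−1.55, SE 0.28, adjusted p = 0.0399). All 5 libraries of the DAV132 arm lay below the CZA mean for each of these genes. No member of a fixed list passed over all genes. Adjusted over the list alone, 40 of 44 oxidative phosphorylation genes, 14 of 18 T cell genes, 14 of 21 MHC class I genes and 10 of 22 T cell activation genes were lower, with Trbc1 at −1.41, Psmb8 at −1.32, Icos at −1.63 and Tnfrsf4 at −1.28. Camera placed these 4 lists below the other genes (adjusted p = 2.29e-07, 0.00186, 0.00229 and 0.00229), and each had adjusted p = 0.808 with an estimated correlation. The repeat entries took 28.2% of the TPM in the DAV132 arm and 9.06% in the CZA arm of this comparison (exact p = 0.0397). Haemoglobin genes stood higher, with Hba-a1 at 1.41 (adjusted p = 0.0748) and 3 of 5 erythroid genes higher when adjusted over the list alone (camera adjusted p = 5.44e-05, and adjusted p = 0.808 with an estimated correlation). The tissue residency list (camera adjusted p = 0.0348) and the immediate early and heat shock list (0.022) were also placed lower, with 6 of 14 and 4 of 24 members when adjusted over the list alone and adjusted p = 0.808 and 0.823 with an estimated correlation. No list in any comparison passed with an estimated correlation, the lowest adjusted p being 0.0971. Cd8a had −0.80 (adjusted p = 0.0928), Gzmb −0.89 (0.0946), Ifng −0.96 (0.0996), Pdcd1 −0.81 (0.153) and Tox −0.03.

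Limma called 0 genes higher and 5 lower in that comparison, with 4338 at an unadjusted p under 0.05 and a median change of all genes of −0.40. The stricter filter gave 44 higher and 1321 lower, array weights 64 and 477, and a fit of only the groups compared 0 and 0, with 2474 at an unadjusted p under 0.05. Libraries 16 and 19 bore on it, since without them the median change was −0.05 and the changes were −1.65 for Hilpda (adjusted p = 0.271), −1.21 for Coa7 (0.0269) and −1.25 for Fosl2 (0.179). With median-ratio scaling they were −1.54 (adjusted p = 0.0829), −1.33 (0.0107) and −1.07 (0.11). The number called was 3993 without library 20, 2221 without library 18, 1375 without library 8, 26 without library 17, 10 without library 7, 2 without library 9 and 0 without library 6, 10 or 16.

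Under the isotype antibody, DAV132 against no DAV132 in CD8 T cells gave 0 calls by limma, with 320 genes at an unadjusted p under 0.05 and a median change of −0.06. Interferon-induced and macrophage genes stood lower in the DAV132 arm as lists, without a member passing over all genes. The macrophage and monocyte list had a mean of −0.61 with Ms4a7 at −1.28 and Adgre1 at −0.92 (camera adjusted p = 6.03e-07). The interferon gamma response list had −0.42 with Cxcl9 at −1.01 (8.20 to 3.16 TPM) and Gbp2 at −0.73 (camera adjusted p = 2.61e-07). The type I interferon response list had −0.35 with Oas1g at −1.26 (camera adjusted p = 6.15e-07). Adjusted over the list alone, 1 of its 37 members was lower, and 0 members of the other two lists were. MHC class II presentation was placed lower as well (mean −0.46, camera adjusted p = 0.00172) and the cell cycle higher (mean 0.12, camera adjusted p = 0.000445). With an estimated correlation the cell cycle had adjusted p = 0.812 and the others named 0.802. Library 11 had 2.60 in log2 units for the macrophage list, against 3.82 or more elsewhere in its group. For MHC class II it had 3.72 against 5.03 or more, so both means rest partly on it. Named genes of smallest p, none of which passed, were Nr2f1 (−2.20), Pld4 (−1.05), Kpna6 (−1.02), Tff1 (1.48), Ccl27a (1.06) and Plk2 (0.87). The count was 1 without library 1 or 3.

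The interaction asked whether the change with anti-PD-1 differed between the FMT arms in CD8 T cells. Limma called 0 genes, with 2036 at an unadjusted p under 0.05 and a median of −0.37 and a lowest adjusted p of 0.175. Coa7 had an interaction of −2.19 (adjusted p = 0.175), which passed without libraries 16 and 19 (0.0391) and with median-ratio scaling (0.0172). Plk2, a stress-responsive kinase, had −2.20 and Trat1, a T cell receptor associated adaptor, had −1.90, both with adjusted p = 0.175. Oxidative phosphorylation genes had a mean interaction of −0.96, with 22 of 44 lower when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.33e-09, and adjusted p = 0.713 with an estimated correlation). The T cell list was also placed lower (mean −0.84, camera adjusted p = 0.00571, and 0.713 with an estimated correlation). Libraries 16 and 19 had the low means of this list given above. The count was 1 without library 8 or 20. Averaged over both antibodies, DAV132 gave 0 calls in the CD8 set, with 2255 genes at an unadjusted p under 0.05 and a median change of −0.22. Serpinb9, an inhibitor of granzyme B, had −1.04 and Pak4, a kinase, had 1.01, both with adjusted p = 0.275. The MHC class I presentation list was placed below the other genes, with 4 of 21 members lower when adjusted over the list alone (camera adjusted p = 0.000193, and adjusted p = 0.828 with an estimated correlation). That count was 2 without library 8 and 1 without library 9.

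Averaged over both FMT arms, transcripts that myeloid cells and NK cells are known for were lower with anti-PD-1 than with isotype in the CD8 set. Klrb1a, a lectin-like receptor of NK cells (ENSMUSG00000030361, chromosome 6, 128609227 to 128623533), fell by 2.05 (SE 0.28, adjusted p = 0.00118). Il1b, the cytokine interleukin 1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), fell by 1.93 (SE 0.38, adjusted p = 0.00826). Cd14, a monocyte receptor for bacterial lipopolysaccharide (ENSMUSG00000051439, chromosome 18, 36725067 to 36726798), fell by 1.86 (SE 0.42, adjusted p = 0.0141), and Apoe, an apolipoprotein of macrophages (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), fell by 1.87 (SE 0.46, adjusted p = 0.0186). Cd83 fell by 1.97 and Ccr7 by 1.73, and the chemokines Ccl12 and Pf4 fell by 1.91 and 1.89. Counts in brackets are adjusted over the list alone. Of the macrophage and monocyte list, 16 of 22 fell (18), and of MHC class II presentation 10 of 12 (11). Of the NK cell list, 8 of 14 fell (9), and of the dendritic cell list 6 of 15 (8). Outside these cell types, 18 of 44 oxidative phosphorylation genes fell (33). So did 13 of 24 immediate early and heat shock genes (16), with Hspa1a at −1.62 and Dusp1 at −1.67. Cell cycle had 9 of 46 lower (16), and glycolysis and hypoxia 6 of 33 (10), with Tpi1 at −0.87 and Ldha at −0.81. With the stricter filter 1502 of 7547 genes fell, so the cell cycle and glycolysis counts alone do not stand apart. Camera placed all of these lists below the other genes (adjusted p between 1.29e-08 and 0.0386), and with an estimated correlation each had adjusted p = 0.869 or 0.947. Among lists that camera did not call, inflammatory cytokines and myeloid recruitment had 6 of 16 members lower and 1 higher (adjusted p = 0.159), gut homing and type 17 had 2 of 10 lower and 1 higher (0.929), and CD4 and regulatory T cell had 2 of 13 lower and 1 higher (0.425).

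Limma called 273 genes higher and 1394 lower for averaged anti-PD-1 in the CD8 set, against 1317 and 1655 with median-ratio scaling, 921 and 1054 without libraries 16 and 19, and 104 and 622 with no filter. The median change of all genes was −0.17. Relative to it, the mean was −0.87 for the macrophage and monocyte list, −0.87 for MHC class II, −0.79 for NK cell and −0.44 for oxidative phosphorylation. The largest rises were Olfr1346, an olfactory receptor (2.80), Myo7a (2.80), Lacc1 (2.59) and C1qtnf1 (2.57), and each of the 10 largest had a dinucleotide repeat stretch in a transcript, against 0 of the 10 largest falls. The number called was 556 without library 8, 764 without library 5, 772 without library 15, 809 without library 3, 895 without library 7, 947 without library 13, 1017 without library 4, 1098 without library 16 and 2801 without library 20.

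In the libraries labelled bulk tumour, anti-PD-1 against isotype in the CZA arm mostly gave rises. Rgs8, a regulator of G protein signalling (ENSMUSG00000042671, chromosome 1, 153653025 to 153700323), rose from 0.213 to 12.3 TPM (log2 change 3.41, SE 0.43, limma adjusted p = 0.00156), and it holds a dinucleotide repeat stretch. Apoo, a protein of mitochondrial cristae (ENSMUSG00000079508, chromosome X, 94367117 to 94417093), rose from 2.27 to 20.4 TPM (3.46, adjusted p = 0.0326). Med7, a subunit of the Mediator complex (ENSMUSG00000020397, chromosome 11, 46436925 to 46442721), rose by 3.56 (adjusted p = 0.0349). Hba-a1, an alpha globin (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465), rose from 0.17 to 11.6 TPM (3.14, SE 0.60, adjusted p = 0.0355). Tstd2 (ENSMUSG00000035495, chromosome 4, 46114746 to 46138694) was listed at 0 in all 5 CZA isotype libraries and averaged 13.8 TPM with anti-PD-1 (adjusted p = 0.00474). The single fall was Uqcrc1, a core subunit of respiratory complex III (ENSMUSG00000025651, chromosome 9, 108936633 to 108949623), from 53.1 ± 8.29 to 8.28 ± 4.09 TPM (SD, n = 5 and 5; −2.67, SE 0.52, adjusted p = 0.0374). The macrophage and monocyte list had a mean of −0.74 with 0 of 23 lower and 1 adjusted over the list alone, and Apoe had 107 and 18.1 TPM (−2.96, adjusted p = 0.0773). The T cell list had a mean of 0.46 with 0 of 18 higher and 1 adjusted over the list alone, Cd3g being at 0.84 (adjusted p = 0.107). Camera called both lists (adjusted p = 8.1e-06 and 0.0465), each with adjusted p = 0.766 with an estimated correlation. Cd8a had 0.34 (adjusted p = 0.603), Ifng 0.59 (0.473) and Havcr2 1.17 (0.391).

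Limma called 37 genes higher and 1 lower there, with 1745 at an unadjusted p under 0.05 and a median change of 0.25, against 17 higher and 7 lower with median-ratio scaling. There were 6 higher and 0 lower both in a fit of only the groups compared and with array weights, 9 and 0 with no filter, and 96 and 1 with a pseudocount of 0.1. The CZA isotype group was the loosest of the set, with correlations within the group of 0.73 to 0.75 against 0.84 to 0.91 in the others, and 9333 to 10542 genes at 1 TPM or more against 10429 to 12212. The number called was 119 without T983, 79 without T991, 77 without T985, 63 without T986, 17 without T988, 10 without T982, 9 without T989, 8 without T984 and 5 without T990.

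DAV132 against no DAV132 under isotype, in the libraries labelled bulk tumour, used the same CZA isotype libraries and gave 15 genes higher and 0 lower by limma, with 1454 at an unadjusted p under 0.05. A fit of only the groups compared gave 0 calls, with 968 genes at an unadjusted p under 0.05, and array weights gave 5. Apoo rose from 2.27 to 34.4 TPM (log2 change 3.98, SE 0.66, adjusted p = 0.0157). Mpv17l2, a mitochondrial ribosome assembly factor (ENSMUSG00000035559, chromosome 8, 70758649 to 70760946), rose from 3.15 to 37.1 TPM (3.18, SE 0.44, adjusted p = 0.00653). Grhpr, an enzyme of glyoxylate metabolism (ENSMUSG00000035637, chromosome 4, 44981395 to 44990734), rose by 3.13 (adjusted p = 0.0157), and Mrpl22, a mitochondrial ribosomal protein, by 3.08 (0.0399). All 4 DAV132 libraries lay above the CZA mean for Apoo, Mpv17l2, Grhpr and Rgs8. The interferon gamma response list had a mean of −0.24 with 0 of 24 members passing (camera adjusted p = 0.0445, and adjusted p = 0.874 with an estimated correlation), Cxcl10 being at −1.38 (adjusted p = 0.561). Of the 37 rises with anti-PD-1 in the CZA arm and these 15, 10 were shared, among them Apoo, Med7, Grhpr, Rgs8 and Tstd2. Both comparisons rest on the same 5 controls. In 50 simulations in which all libraries, controls included, were redrawn without a change, no overlap reached above 0. With nothing changed few genes are called at all, and values varied independently between genes with the same spread in all groups. The simulated overlap therefore cannot show how many shared calls these controls bring about. Independent lists of these sizes would share 0.0416, a number that leaves the shared controls out. With the controls split between the comparisons in 20 ways, 1 to 6 genes were shared, with a median of 3.5. The covariance of the fold changes was 0.404, against 0.192 in the simulations and a median of 0.0721 with split controls. The median change of all genes was 0.21, and the number called was 73 without T985, 44 without T983, 37 without T991, 27 without T986, 9 without T027, 7 without T022 and 5 without T024.

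With DAV132, Tnfaip3, Ptges3, Rpl4 and Bhlhe40 were among the genes lower with anti-PD-1 than with isotype in the libraries labelled bulk tumour. Tnfaip3, the NF-kB inhibitor A20 (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657), fell from 139 ± 56.8 to 30.6 ± 13.3 TPM (SD, n = 4 and 5; log2 change −2.19, SE 0.38, limma adjusted p = 0.0179). Ptges3, a co-chaperone of HSP90 (ENSMUSG00000071072, chromosome 10, 128058954 to 128077272), fell from 1696 to 426 TPM (−1.98, adjusted p = 0.0212). Rpl4, a ribosomal protein (ENSMUSG00000032399, chromosome 9, 64173375 to 64178666), fell from 1831 to 669 TPM (−1.48, SE 0.24, adjusted p = 0.0179). Bhlhe40, a transcription factor of activated and resident T cells, fell from 182 to 66.3 TPM (−1.45, adjusted p = 0.0355), the only member of the tissue residency list to do so, with 3 lower when adjusted over the list alone. Of 44 oxidative phosphorylation genes, 1 fell, Ndufa4 (485 to 190 TPM, −1.38, adjusted p = 0.0489), and 9 were lower when adjusted over the list alone. None of the immediate early and heat shock genes passed over all genes and 5 of 24 did when adjusted over the list alone, Dusp1 being at −2.63 (adjusted p = 0.0647). The dendritic cell list had a mean of −0.92 with 2 of 14 lower when adjusted over the list alone. The camera adjusted p values of these 4 lists were 0.00403, 9.53e-09, 1.15e-06 and 0.0152, and with an estimated correlation they had adjusted p = 0.434, 0.316, 0.316 and 0.209. Cholesterol synthesis had a mean of −0.73 with 0 of 22 lower and 3 adjusted over the list alone (camera adjusted p = 0.000477, and adjusted p = 0.316 with an estimated correlation). Pdcd1 had −0.87 (adjusted p = 0.447) and Tcf7 −1.65 (0.0979).

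Limma called 4 genes higher and 28 lower in that contrast, against 65 and 39 with TPM rescaled without repeat entries, 132 and 176 with array weights, and 2 and 4 in a fit of only the groups compared. There were 1370 genes at an unadjusted p under 0.05, the median change was −0.15, and the 4 rises were predicted genes or others outside the rule for names. Without T985 and the repeat-rich T026, Tnfaip3 (adjusted p = 0.0455) and Rpl4 (0.0401) still passed, while the other falls named here did not. The number called was 132 without T029, 20 without T030, 13 without T028, 11 without T023, 5 without T021, 1 without T022 and 0 without T024 or T027.

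Under anti-PD-1, DAV132 against no DAV132 in the libraries labelled bulk tumour gave 0 calls by limma, with 1010 genes at an unadjusted p under 0.05 and a median change of −0.19. Array weights gave 15 higher and 27 lower. The lowest adjusted p, 0.0589, was that of a predicted gene and of pseudogenes of ribosomal proteins. Among genes within the rule for names the lowest belonged to ribosomal protein genes, with Rpl6 at −1.06 (0.0841), Rpl4 at −1.16 (0.102) and Rpl5 at −1.35 (0.102). T cell genes stood lower as lists, with Ctla4, an inhibitory receptor, at 195 and 43.5 TPM (−2.04, adjusted p = 0.218) and Icos, a co-stimulatory receptor, at 235 and 85.7 TPM (−1.55, adjusted p = 0.274). The T cell activation list had a mean of −0.67 and 2 of 22 lower when adjusted over the list alone, and the inhibitory receptor and exhaustion list a mean of −0.64 and 3 of 21. Camera gave adjusted p = 6.8e-05 and 0.00128, and these had adjusted p = 0.317 and 0.378 with an estimated correlation. The erythroid list had a mean of 1.07 and 1 of 7 higher when adjusted over the list alone (camera adjusted p = 0.000292, and adjusted p = 0.0971 with an estimated correlation), Hba-a2 being at 2.60 (adjusted p = 0.317). Without T029 there were 8 calls, with 4 without T989, 2 without T026 and 1 without T023.

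The interaction in the libraries labelled bulk tumour had 6 calls, all negative, so that the change with anti-PD-1 was lower in the CZA+DAV132 arm than in the CZA arm. They were Rab4a, a GTPase of endosome recycling (ENSMUSG00000019478, chromosome 8, 123805985 to 123835287; −4.48, SE 0.82, limma adjusted p = 0.0462), Tstd2 (−4.40), Rgs8 (−3.97), Grhpr (−3.85), Mpv17l2 (−3.81) and the predicted gene D030056L22Rik (−4.14), and none passed with median-ratio scaling. The median interaction of all genes was −0.42, and 1375 genes had an unadjusted p under 0.05. The T cell list had a mean of −0.98 with 0 of 18 members passing either over all genes or adjusted over the list alone (camera adjusted p = 5.24e-05, and adjusted p = 0.584 with an estimated correlation). Without T985 there were 18 calls, 14 without T983, 2 without T989 and 0 without T986, T982, T984, T990, T022, T024, T027, T021, T023 or T026. DAV132 averaged over both antibodies gave 0 calls by limma, with 1177 genes at an unadjusted p under 0.05, a median change of 0.03, and 1 call without T983, T985, T987, T991 or T027. Erythroid genes had a mean of 1.00 in that contrast, with 0 of 7 passing over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00178, and adjusted p = 0.169 with an estimated correlation), and the list of T cell recruiting chemokines had a mean of −0.33 (camera adjusted p = 0.0241, and adjusted p = 0.449 with an estimated correlation).

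Averaged over both FMT arms, Hba-a1 was higher with anti-PD-1 by 2.88 (SE 0.44, limma adjusted p = 0.0177) in the libraries labelled bulk tumour, and the chemokine receptor genes Ccr7 and Cxcr4 were lower. Ccr7 fell by 1.56 (SE 0.37, adjusted p = 0.0443), and Cxcr4, the receptor of CXCL12 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293), fell by 1.49 (SE 0.32, adjusted p = 0.0274). Fdps, an enzyme of isoprenoid and sterol synthesis (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), fell by 1.29 (adjusted p = 0.0243), Ptges3 by 1.44 (0.0177) and Atad3a, a mitochondrial membrane ATPase, by 2.31 (0.0226). Ndufa4 (ENSMUSG00000029632, chromosome 6, 11900292 to 11907497; −1.03) and Uqcrq (−0.95) were the 2 of 44 oxidative phosphorylation genes that fell, and 7 did when adjusted over the list alone (camera adjusted p = 4.18e-07, and adjusted p = 0.406 with an estimated correlation). The macrophage and monocyte list had a mean of −0.71, with 0 of 23 lower over all genes and 3 adjusted over the list alone (camera adjusted p = 1.44e-05, and adjusted p = 0.406 with an estimated correlation). Limma called 69 genes higher and 73 lower, against 179 and 90 with TPM rescaled without repeat entries and 123 and 168 with median-ratio scaling, with a median change of 0.07. With no filter 17 were higher and 26 lower. Without T985 and T026 Ccr7 had an adjusted p of 0.0716. The number called was 0 without T027, 23 without T990, 30 without T021, 53 without T022, 65 without T024, 67 without T984, 87 without T989 and 92 without T028.

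The averaged anti-PD-1 changes were compared between the sets, which come from separate experiments. Across 12126 genes tested in both, Pearson's r was 0.324 and Spearman's rho 0.326, a correlation across genes, which are not independent replicates. Within CZA+DAV132 r was 0.491, and within CZA 0.167. Of the genes called in both sets, 33 fell in both, where 8 would be shared by independent lists, and 11 rose in both, where 1.27 would be. These expected numbers take every gene as equally likely to be called. In the CD8 set falls were more frequent among genes of higher level, 1502 of 7547 with the stricter filter against 1394 of 12942. Part of the excess may therefore come from level alone. Ccr7 fell by 1.73 in the CD8 set and 1.56 in the libraries labelled bulk tumour, Cxcr4 by 0.78 and 1.49, Fdps by 1.14 and 1.29 and Ndufa4 by 1.06 and 1.03. Zfp748, a zinc finger gene, was the single gene called in opposite directions (−0.65 and 1.81). Without libraries 16, 19, T985 and T026 and with median-ratio scaling, r was 0.283, and 78 genes fell and 13 rose in both. Independent lists would share 17.8 and 7.25. That setting kept CD8 library 1 (25.2% of its TPM in repeat entries) and the other CZA+DAV132 anti-PD-1 CD8 libraries (11.5% or more).

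**Figure D4:**
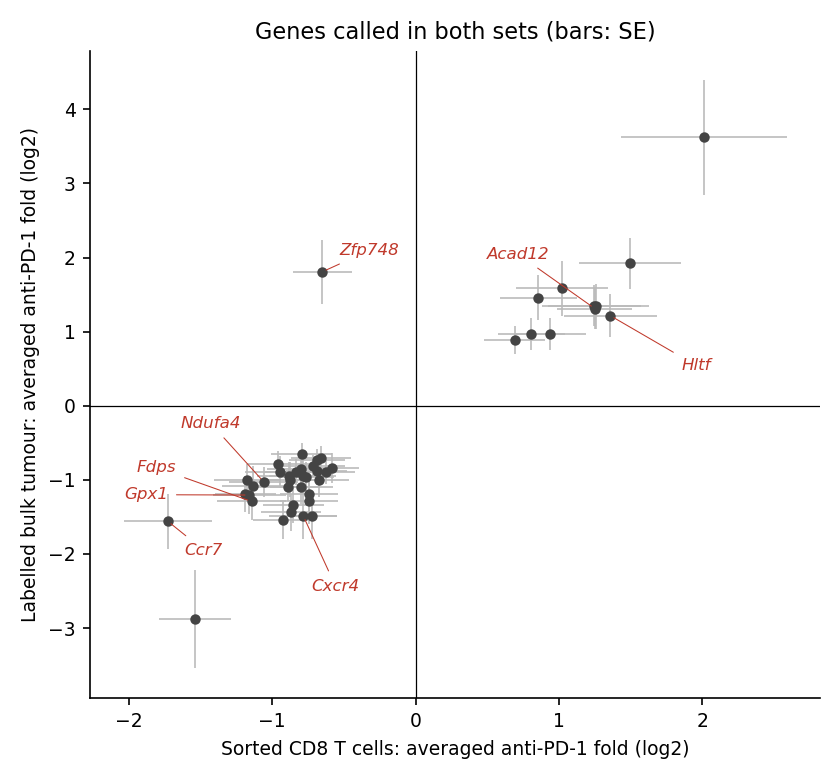
Log2 change with anti-PD-1, averaged over both FMT arms, in the CD8 set (horizontal) and in the libraries labelled bulk tumour (vertical), for the 45 genes called in both sets, a dot per gene with bars of the standard error. Of these genes 33 fell and 11 rose in both sets, and Zfp748 (−0.65 and 1.81) lies apart.

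Variable segments of the T cell receptor beta chain lie outside the rule for named genes and were examined after their values had been seen. Their summed level was expressed per 100 TPM of Cd3d, Cd3e and Cd3g, which encode other chains of the receptor complex. In CD8 T cells of the CZA+DAV132 arm it was 35.7 ± 8.06 with isotype and 15 ± 5.35 with anti-PD-1 (SD, n = 5 and 5; exact two-sided permutation p = 0.00794, adjusted p = 0.0212 over 8 tests). The repeat share separated the same libraries, at 2.26% to 8.28% with isotype and 11.5% to 69.2% with anti-PD-1. Over the 20 CD8 libraries, with log2 values centred by group, the ratio ran lower where the repeat share was higher (Pearson's r = −0.487, permutation p = 0.0336, adjusted p = 0.0672 over both sets, and Spearman's rho = −0.627, permutation p = 0.00929, adjusted p = 0.0186). Without libraries 5 and 19, the farthest in repeat share, r was −0.761. Over the 19 libraries labelled bulk tumour r was 0.264 (permutation p = 0.509) and rho 0.135 (0.657), and r was 0.134 without T026 and T985. In the libraries labelled bulk tumour it was 7.93 ± 3.45 (n = 4) and 2.02 ± 1.26 (n = 5) in the CZA+DAV132 arm, and 18.6 ± 5.85 and 5.53 ± 2.55 (n = 5 and 5) in the CZA arm, each with an exact p of 0.00794, the smallest these group sizes allow, and an adjusted p of 0.0212. In CD8 T cells of the CZA arm it was 42.4 ± 13.8 and 29.4 ± 13 (n = 5 and 5; exact p = 0.167, adjusted p = 0.191). The 4 comparisons of DAV132 with no DAV132 had adjusted p values of 0.0634 or more.

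**Figure D5:**
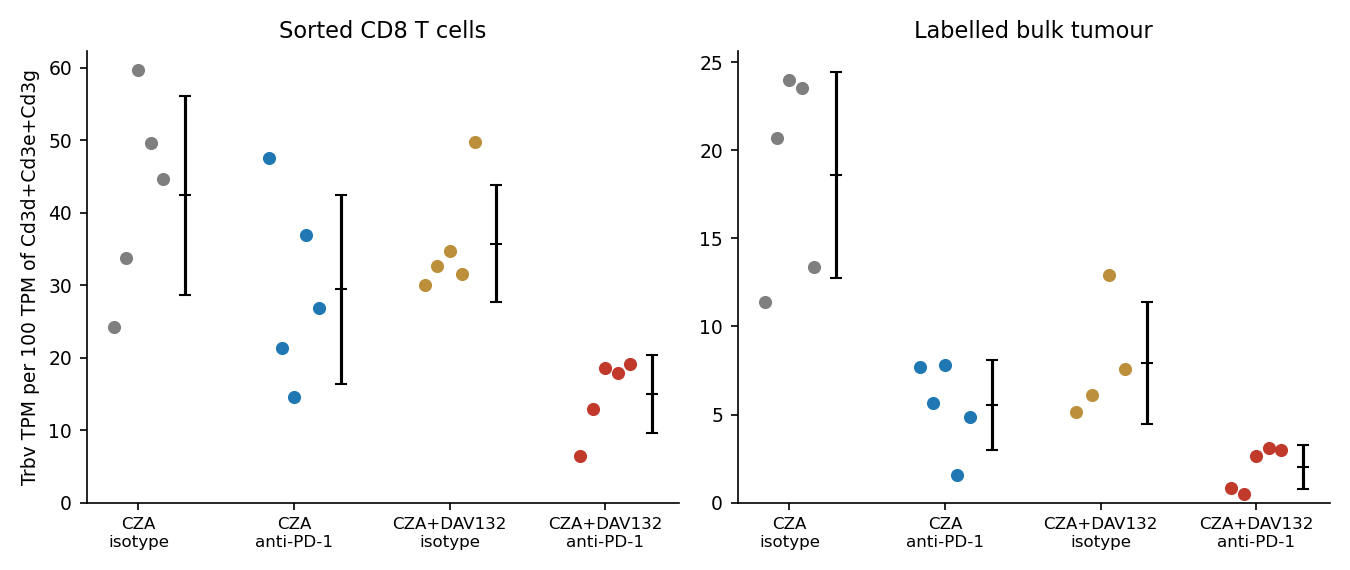
Summed TPM of T cell receptor beta variable segments per 100 TPM of Cd3d, Cd3e and Cd3g in each library (points), with bars at the group mean and lines for the SD, for the 4 groups of each set. In the CZA+DAV132 arm the anti-PD-1 libraries lie below the isotype libraries in both sets, with means of 15 and 35.7 in CD8 T cells and 2.02 and 7.93 in the libraries labelled bulk tumour.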

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

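The tests of tumour tissue rich in T cells, of T cell libraries under the bulk tumour label, of the same libraries in both sets, of the repeat share and of libraries 16 and 19, of a lower T cell share in the CZA isotype group, and the counts over other splits were chosen only after the results they bear on were seen.

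The libraries labelled bulk tumour carried a T cell profile. Tumour tissue with many T cells is argued against by the summed T cell list, which was a median of 14.9 times the fibroblast and fibrosarcoma list although MCA-205 cells are fibrosarcoma cells. A second candidate explanation, T cell libraries under the bulk tumour label, stays open, since by mean log2 level the highest of the 13 cell type lists other than T cell lay 0.276 above the CD8 set, but most members are near 0, and by summed TPM the endothelial list lay 1.67 and the fibroblast list 1.26 above it (−0.0606 and 0.808 without Pecam1 and Thy1, which T cells also express). That the same libraries entered both sets is argued against by a highest correlation between them of 0.874, under the median of 0.948 within the CD8 set, but the bar was moved there from the lowest correlation within the CD8 set, 0.806, after the value was seen, and against that it would have decided nothing. Actb, at 36590 to 170900 TPM in the libraries labelled bulk tumour and 1314 to 6782 TPM in the CD8 set, also speaks against it. No biological explanation other than tumour tissue with many T cells was tested.

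Anti-PD-1 in the CZA+DAV132 arm of the CD8 set, where 3042 genes were called, coincided with a high repeat share. The loss of TPM to repeat entries as the whole cause is argued against by 2614 calls after rescaling without them, and libraries 16 and 19 as the whole cause by 1207 calls without these libraries. Reads of repeats assigned to other genes may account for part of the rises, since 50% of the genes that rose with an annotated transcript held a dinucleotide repeat stretch, against 5.66% of those that fell and 10.6% of those not called. The falls stay open between an effect of anti-PD-1 and RNA quality that moved with the group, which the design cannot separate.

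Calls against the CZA isotype group of the libraries labelled bulk tumour were mostly rises, 37 and 15, from libraries with fewer genes detected. For a lower share of T cells in that group, the T cell list changed by 0.459, in the direction such a share would give, against a median rise of 2.91. The rises were picked for passing in the same data, where small changes rarely pass, so a moderate shift in T cell share would lie below them in any case. The comparison does not decide, and a lower share stays open. For random loss of transcripts in each library, genes at 0 in all 5 libraries were 2180 times as many as independent losses within classes of like level would give, 5 against 0.0023, which passed the bar set in advance against it. That bar was wrong for these calls, because only 1 of the 42 genes that rose is among those 5 genes and the other groups of 5 libraries held 2 and 1 such genes, so random loss stays open, as does an effect of the treatments. The share of genes at 0 ran from 1.46% to 4.67% in the CZA isotype libraries and from 0.135% to 1.33% in the others, among 8009 genes.

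Other splits of the same libraries, 100 per comparison with the real one included, were fitted to see whether chance can be excluded. In the CD8 set, only the real split reached 3042 calls for anti-PD-1 in CZA+DAV132 (highest other 1207) and 1667 for averaged anti-PD-1 (highest other 293). With 100 splits this makes chance unlikely there but does not exclude it. For anti-PD-1 in CZA, 3 splits gave the real 2 or more, and as another gave 250, chance is not taken as excluded for that count, which was 0 or 1 with any library left out. For DAV132 under anti-PD-1, 5 splits gave the real 5 or more (highest other 3325), so chance cannot be excluded. A split that calls 3325 genes where the real one calls 5 points to a structure of the samples other than the groups, and so does the 250 against 2. Among the libraries labelled bulk tumour, only the real split reached the count for anti-PD-1 in CZA (38, highest other 27). The same held, with the same limit, for the interaction (6, highest other 2) and averaged anti-PD-1 (142, highest other 2). These counts still rest on single libraries, being 5 without T990 for anti-PD-1 in CZA, 0 without any of 10 libraries for the interaction and 0 without T027 for averaged anti-PD-1. For anti-PD-1 in CZA+DAV132 the real count or more came from 2 splits (32), and as another gave 101, chance is not taken as excluded there either. For DAV132 under isotype the real count or more came from 9 splits (15, highest other 85), so chance cannot be excluded. The 101 against 32 and the 85 against 15 again point to a structure of the samples. Where the real count was 0, all 100 splits gave as many, with a highest other of 59 for DAV132 under isotype in the CD8 set and 2 for the other four comparisons of that kind.

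Single libraries that stood far from the rest of their group were found in 13 of 158 tests, where chance gives about 7.9. CD8 library 5 had 180 TPM of Pdcd1 and 2570 TPM of Gzmb, against means of 101 and 1190 TPM in the other 4 libraries of its group. CD8 library 20 had 3.23 TPM of Foxp3, against 0.602. CD8 library 11 had a scaling factor of 1, against 1.1. T983 had 166 TPM of Pdcd1 against 125, and T984 had 1.23 TPM of Foxp3 against 0. T022 had 2.44 TPM of Cxcl10 against 42.9. T023 had 16.4 TPM of Lag3 against 68 and 17.8 TPM of Cd274 against 35.9, and T026 had 13.1 TPM of Mki67 against 27.6. The repeat share was 13.5% in T985 against 0.0614%, 0.422% in T988 against 0.0486% and 50.9% in T026 against 0.0605%.

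The change with anti-PD-1 differed between the FMT arms, by the interaction test in limma, for 6 genes in the libraries labelled bulk tumour: Rab4a (−4.48), Tstd2 (−4.4), D030056L22Rik (−4.14), Rgs8 (−3.97), Grhpr (−3.85) and Mpv17l2 (−3.81). All but Rab4a are among the 10 genes that lay lower in the CZA isotype group than in both groups compared with it, and the count was 0 with median-ratio scaling and without any of 10 libraries. Camera with a preset correlation gave such a difference for lists in the CD8 set, each with adjusted p = 0.713 or 0.761 with an estimated correlation, with mean interactions of −0.956 for oxidative phosphorylation, −0.905 for immediate early and heat shock, −0.879 for tissue residency, −0.839 for T cell activation, −0.835 for T cell and −0.606 for cholesterol synthesis. In each of these lists the repeat-rich libraries 16 and 19 had the lowest means of the CD8 set. For the T cell list they had 6.46 and 6.60 in log2 units, against 7.87 or more in the rest. On the higher side, with adjusted p = 0.713 with an estimated correlation, were erythroid cell (0.744), fibroblast and fibrosarcoma (0.244), macrophage and monocyte (0.141), TGF beta and matrix remodelling (0.13), type I interferon response (0.0913) and interferon gamma response (0.00352, with a median of −0.10). Mean interactions in the libraries labelled bulk tumour, each with adjusted p = 0.584 with an estimated correlation, were −0.975 for T cell, −0.956 for T cell activation, −0.949 for immediate early and heat shock, −0.948 for cholesterol synthesis, −0.944 for tissue residency and −0.616 for oxidative phosphorylation, with fibroblast and fibrosarcoma at 0.394 and type I interferon response at 0.0483. For the T cell list, T023 and T026 of the CZA+DAV132 anti-PD-1 group had 6.62 and 7.19 in log2 units. Every other library of that set had 7.48 or more.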

How the results depend on the processing

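The fits without libraries 16 and 19, without T985 and T026, and without repeat entries were chosen only after the results were seen. Numbers of calls are given in the order DAV132 under anti-PD-1, DAV132 under isotype, anti-PD-1 in CZA, anti-PD-1 in CZA+DAV132, interaction, averaged DAV132 and averaged anti-PD-1. In the CD8 set the calls as reported were 5, 0, 2, 3042, 0, 0 and 1667. They were 1, 0, 2, 2973, 0, 0 and 1580 with a pseudocount of 0.1, 0, 0, 0, 2310, 0, 0 and 726 with no filter, and 1365, 0, 2, 2901, 0, 0 and 1701 with the stricter filter. With median-ratio scaling they were 3, 3, 5, 3291, 1, 3 and 2972, and with TPM rescaled without mitochondrial genes and small RNAs 4, 0, 0, 2413, 0, 0 and 1064. Array weights gave 541, 3, 3, 3467, 6, 8 and 3056. Without libraries 16 and 19 they were 2, 2, 6, 1207, 1, 5 and 1975, with 823 of the 1207 among the 3042, and with scaling besides 3, 2, 6, 2003, 0, 4 and 2740. Without repeat entries they were 5, 3, 2, 2614, 1, 2 and 2285, of which 1349 were higher and 1265 lower for anti-PD-1 in CZA+DAV132 and 1028 and 1257 for averaged anti-PD-1. A fit of only the groups compared gave 0, 2, 2 and 1281 for the pairwise contrasts, in which fewer libraries inform the spread.

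For the libraries labelled bulk tumour the calls as reported were 0, 15, 38, 32, 6, 0 and 142. They were 4, 31, 97, 32, 5, 0 and 167 with a pseudocount of 0.1, 1, 11, 9, 14, 3, 0 and 43 with no filter, and 0, 13, 24, 57, 3, 0 and 187 with the stricter filter. With median-ratio scaling they were 2, 13, 24, 37, 0, 0 and 291, and without mitochondrial genes and small RNAs 0, 15, 35, 24, 7, 0 and 132. Array weights gave 42, 5, 6, 308, 4, 1 and 212. Without T985 and T026 they were 2, 47, 78, 14, 11, 1 and 204, and without repeat entries 1, 13, 46, 104, 1, 0 and 269. For anti-PD-1 in CZA+DAV132 the split was 10 higher and 27 lower with scaling and 65 and 39 without repeat entries, against 4 and 28 as reported. A fit of only the groups compared gave 1, 0, 6 and 6. Apart from the fits with fewer libraries or genes, the cause of these differences was not tested.

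With each library left out in turn, the calls in the CD8 set ran from 0 to 3993 for DAV132 under anti-PD-1, 0 to 1 for DAV132 under isotype, 0 to 1 for anti-PD-1 in CZA, 1795 to 4451 for anti-PD-1 in CZA+DAV132, 0 to 1 for the interaction, 0 to 2 for averaged DAV132 and 556 to 2801 for averaged anti-PD-1. The calls in the libraries labelled bulk tumour ran from 0 to 8, 5 to 73, 5 to 119, 0 to 132, 0 to 18, 0 to 1 and 0 to 196 in the same order. Leaving out library 6, 9, 10 or 16 ended the calls of Hilpda (adjusted p = 0.0902, 0.0933, 0.0822 and 0.131), Coa7 (0.0902, 0.0685, 0.0796 and 0.122) and Fosl2 (0.0902, 0.117, 0.0796 and 0.131), and leaving out library 19 those of Hilpda (0.104) and Fosl2 (0.076). For anti-PD-1 in CZA+DAV132 of the CD8 set, Ccl17, Csf2, Dusp1, Cd83, Ccr7, Klra1 and Ndufa4 passed without each library, with highest adjusted p between 0.0117 and 0.0233, and Cxcl9 failed without library 11, 12, 15, 16 or 17 (0.0674, 0.0571, 0.0527, 0.0939 and 0.0596). For anti-PD-1 in CZA+DAV132 of the libraries labelled bulk tumour, Tnfaip3 failed without T022, T024, T027 or T028 (0.0735, 0.0616, 0.0928 and 0.0722), and Rpl4 without T022, T024 or T027 (0.0588, 0.0616 and 0.0928). For anti-PD-1 in CZA, Uqcrc1 failed without T982, T984, T988, T989 or T990 (0.0658, 0.0599, 0.0674, 0.0794 and 0.0542). For averaged anti-PD-1, Fdps, Ptges3 and Hba-a1 failed without T027 (0.0638, 0.0574 and 0.0574).

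Over the other alternatives the adjusted p ran from 0.02 to 0.271 for Hilpda, 0.00417 to 0.168 for Coa7 and 0.02 to 0.203 for Fosl2. In anti-PD-1 in CZA+DAV132 of the CD8 set it ran from 0.00222 to 0.0557 for C1qtnf1, 0.00386 to 0.168 for Myo7a, 0.0125 to 0.139 for Cxcl9, 0.0036 to 0.329 for Tox, 0.0108 to 0.362 for Havcr2 and 0.0187 to 0.171 for Cd274. The interaction of Coa7 had 0.0172 to 0.338. In the libraries labelled bulk tumour it ran from 0.00666 to 0.0991 for Tnfaip3, 0.00482 to 0.0979 for Rpl4 and, averaged over the arms, 0.0249 to 0.0718 for Ccr7.

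No named gene that passed turned its direction under any alternative. Apart from single libraries left out, 5483 values of named genes kept their direction and side of the threshold, 202 that had passed did not, 110 passed that had not, and 511 that had not passed moved by more than their standard error or passed in the other direction. For lists, 1346 camera results were kept, 232 were lost and 20 gained, and 2 turned, the fibroblast and fibrosarcoma list without libraries 16 and 19, for DAV132 under anti-PD-1 (adjusted p = 0.552) and the interaction (0.966) in the CD8 set. Without library 14 the immediate early and heat shock list turned for DAV132 under isotype in the CD8 set (0.928), and over all libraries left out its adjusted p ran from 2.26e-05 to 0.928. No paired analysis was possible because each replicate name belongs to a single library. Sequencing depth is unknown, so no value could be set against its counting error.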

Other observations

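The tests of T cell receptor beta levels relative to Cd3 and against the repeat share, and the settings without 4 repeat-rich libraries were chosen only after the T cell receptor values and the repeat shares were seen.

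Of the genes lower with anti-PD-1 in both sets, averaged over the FMT arms, several not yet described are given here without a test of any shared function. Eif6, a factor of ribosome assembly, changed by −1.13 in the CD8 set and −1.08 in the libraries labelled bulk tumour, and Eif5a, a translation factor, by −1.17 and −0.996. Odc1, the enzyme that opens polyamine synthesis, changed by −0.877 and −0.998. Gpx1, a peroxidase that removes hydrogen peroxide, changed by −1.16 and −1.21, Cst3, a secreted protease inhibitor, by −1.19 and −1.19, and Timm17a, part of the import channel of the inner mitochondrial membrane, by −0.85 and −1.34. Among genes that rose in both sets were Hltf, a DNA repair helicase (1.36 and 1.22), Ctcfl, a germline paralogue of the insulator protein CTCF (1.26 and 1.34), and Brpf1, a chromatin reader (0.81 and 0.97). All these genes passed in both sets (limma adjusted p under 0.05), and they were chosen after their values were seen.

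Libraries rich in repeat reads in the CZA+DAV132 anti-PD-1 group of both sets were a possible explanation for the shared changes. Without libraries 16, 19, T985 and T026 and with median-ratio scaling the correlation across genes was 0.283, against 0.324 as deposited. T985 belongs to the CZA isotype group. This argues against these 4 libraries as the whole cause. It does not decide on the repeat share, since the CD8 libraries kept in the CZA+DAV132 anti-PD-1 group still had 11.5% or more. The isotype libraries of that arm had at most 8.28%. Of the 45 genes called in both sets as deposited, 38 were also among the 92 called in both under that setting. Those lost include Eif6 (change −1.08 to −1.04, limma adjusted p = 0.0595) and Hltf (1.22 to 1.21, 0.058) in the libraries labelled bulk tumour. Brpf1 (0.97 to 0.95, 0.073) and Ccr7 (−1.56 to −1.52, 0.0541) were lost there too. In the CD8 set Brpf1 went only from 0.81 to 0.67 (0.0806). The matching correlation for anti-PD-1 in CZA+DAV132 went from 0.491 to 0.391, and for DAV132 under anti-PD-1 from 0.453 to 0.313. For anti-PD-1 in CZA it went from 0.167 to 0.12 with 0 genes called in both, near DAV132 under isotype (0.171 to 0.118). The agreement was thus stronger in the CZA+DAV132 arm, and a shared response to anti-PD-1 remains a hypothesis.

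Transcripts of antigen-presenting cells in the sorted CD8 libraries may come from carried-over cells in varying number. If so, the macrophage and monocyte genes should vary together among libraries of a group. Their mean residual correlation was 0.582 over 22 genes, above each of 1000 random lists matched on level, whose median was 0.328 and highest 0.534. The sort on CD8 should remove such cells, and Lyz2 still had a median of 136 TPM. The same measure was taken for 6 other lists. It was 0.71 for fibroblast and fibrosarcoma genes, above each random list (highest 0.448), and 0.826 for the T cell list, which 1 of 1000 random lists reached. It was 0.642 for MHC class II presentation, which 43 reached, 0.698 for erythroid cell (207), 0.176 for dendritic cell (335) and 0.458 for NK cell (739), so the dendritic, NK and erythroid genes did not stand apart from random lists. The T cell list did so without being carried over, so a high value alone does not single out carried-over cells. Whether anti-PD-1 lowers the number of such cells in the tumour, their uptake with T cells in the sort, or their expression was not tested.

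The lower level of T cell receptor beta variable segments with anti-PD-1 in the CZA+DAV132 arm could come from repeat-rich libraries or from scaling. Relative to Cd3d, Cd3e and Cd3g, which a scaling factor for each library moves alike, all 10 anti-PD-1 libraries of the arm, 5 in each set, lay below every isotype library of their set, so such a factor cannot be the cause. This also met the bar set in advance against repeat-rich libraries, but that bar was wrong, because in the CD8 set the repeat share itself separates these groups. There the ratio ran lower within groups where the repeat share was higher (r = −0.487, permutation p = 0.0336, adjusted p = 0.0672, and rho = −0.627, adjusted p = 0.0186), so repeat reads, or whatever goes with them, remain a candidate explanation. In the libraries labelled bulk tumour, the 4 anti-PD-1 libraries of the arm with under 1% of their TPM in repeats, 0.041% to 0.0746% against 0.0423% to 0.0679% with isotype, all lay below every isotype library, which argues against repeat reads as the cause in that set. The summed TPM of the segments was 1570 with isotype and 514 with anti-PD-1 in the CD8 set (exact p = 0.00794, adjusted p = 0.0635). The constant regions relative to Cd3 were 154 ± 8.67 and 123 ± 31.4 (SD, n = 5 and 5; exact p = 0.0317, adjusted p = 0.254). Fragmented RNA as a cause was not tested. That anti-PD-1 or DAV132 changes how uneven the segments are was tested on the share of the largest segment, and the lowest adjusted p of 8 exact tests was 0.27. This met the bar set in advance against a change, but a p that misses the threshold with 4 or 5 libraries per group does not exclude a change, so the question stays open. The largest segment took 14% ± 2.79 of the total with isotype and 20.2% ± 5.57 with anti-PD-1 in CD8 T cells of the CZA arm (n = 5 and 5; exact p = 0.0714, adjusted p = 0.27).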
